A study of Homo sapiens with 6 samples.

How the data were processed

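Gene expression was measured in HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. According to the labels, cells were left untransfected or were transfected with 2 µg or 4 µg of a plasmid carrying the cloned miR-23a27a24-2 cluster, whose single transcript gives miR-23a, miR-27a and miR-24. The labels list 6 arrays in 3 groups of 2 biological duplicates. The control was untransfected, and no group received an empty plasmid. All 6 arrays lay on 1 bead chip, with the 4 µg group in the first pair of positions, the 2 µg group in the next pair and the control in the last pair, so position on the chip and group cannot be told apart from the labels.

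Per the labels, total RNA was amplified, labelled with biotin, stained with streptavidin Cy3 and hybridized to Illumina Human-6 arrays, and the submitters used BeadStudio, whose version is not given in the sources used here. The deposited scanner values are the mean bead intensity of each of 48701 probes on each array, not normalized and with no background subtracted. The standard error of the bead intensity in the deposited values is on the same scale. The detection p-value per probe and array is, per the file headers, the one BeadStudio gives, a share of negative control beads at least as bright. Bead numbers per probe were also deposited. The authors' processed table also holds an intensity on the linear scale. On each array it was a straight-line function of the scanner value, with a background subtracted and 1 factor per array that gave all arrays a mean of 238.3; this was found from the values, and the software step behind it is not given in the sources used here.

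The scanner values were processed in R 4.3.3 with limma 3.58.1. The neqc function estimated the background of each array from the detection p-values, subtracted it by a normal-exponential model, added an offset of 16, normalized the arrays to the same quantiles and took log2. The reference table gave 1 gene symbol for 23687 probes, several symbols for 35 probes and none for 24979 probes. Of the probes with 1 symbol, 23651 were found in the second reference table, which changed 0 symbols. A probe was kept if its detection p-value was under 0.01 on both arrays of at least 1 group. This left 10021 probes, of which 8455 had 1 symbol. Each gene was represented by its kept probe with the highest mean signal, which gave 8018 tested genes of 18774 on the arrays. Several kept probes existed for 389 genes. Among these, probes of the same gene were called in opposite directions for 3 genes at 2 µg and for 1 gene at 4 µg.

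The 3 groups were fitted together by limma with a moderated variance, with 3 residual degrees of freedom and 7.42 prior degrees of freedom. A lone fit of duplicates would estimate the spread of each gene from even fewer arrays, and the number of arrays limits the precision of every value. The comparisons were 2 µg against control, 4 µg against control, 4 µg against 2 µg, and the mean of both doses against control. A gene was called at an adjusted p under 0.05 after the Benjamini-Hochberg adjustment over all tested genes, with two-sided tests. Counts over 1.5-fold describe the called genes and were not tested against that fold. The relation of the doses was described by the correlation across genes of their log2 fold changes. Because both doses share the control arrays, it was set against 100 simulations in which no gene differed. Genes are not independent replicates, and these values carry no p.

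Lists of genes were taken from general knowledge and were tested by camera with a preset correlation between genes of 0.01, adjusted over the 26 lists of each comparison. The lists were published targets of miR-23a, of miR-27a and of miR-24, endoplasmic reticulum chaperones and the unfolded protein response, ATF4 and the integrated stress response, apoptosis, the immediate early and JNK response, p53 targets, the interferon response, the NF-kB response, G1/S and DNA replication, G2/M and mitosis, histone genes, cholesterol synthesis, the cytosolic heat shock response, oxidative phosphorylation, cytosolic ribosomal proteins, the proteasome, glycolysis and hypoxia, oxidative stress and metallothioneins, microRNA machinery, TGF-beta and BMP signalling, and markers of haematopoietic, fibroblast, epithelial and neuronal cells. Some genes stand on several lists. Camera with a correlation estimated per list and fry, which tests whether the members move on balance in one direction, were run beside it. Members were also adjusted over the list alone.

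Named genes were chosen by rule. They were the 10 genes with the largest rise and the 10 with the largest fall at each dose against the control, and 5 of each for 4 µg against 2 µg, among called genes with both arrays of 1 group above both of the other. From each list they were the 4 members with the smallest p at 4 µg and the 2 with the smallest p at 2 µg. XIAP, FADD, TRIB3, DDIT3, HSPA5, GAPDH and ACTB were always named, and symbols of predicted or unnamed transcripts were passed over. A gene outside the rule is described where it stands as chosen after its values were seen. Where no array of a group detected a gene, the fold is a lower bound. On each array of the undetected group, the signal was raised to at least the lowest normalized signal of any probe detected on that array before the fold was taken, and such folds are written as at least N-fold.

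The groups, the comparisons, the lists, the rule for named genes and most alternatives were fixed before the data were examined. The alternatives were normexp background correction with an offset of 50, no background correction, median scaling over all probes, the authors' processed values, no detection filter, detection on all 6 arrays, every probe tested on its own, an intensity trend in the variance, a fit of only the groups compared, the replicate number as a block, an estimated correlation in camera, and leaving out each array in turn. Median scaling over the tested genes, and leaving out arrays for the correlation of the doses, were added after the data were seen. When an array was left out, the lone array of its group was assumed to vary like the other groups. Leaving out either array of the group not compared gave the same fit as that of only the groups compared. Losses of a call in these settings are therefore not separate results. A test of seed matches in 3′ UTRs was planned, but it was not run because 3′ UTR sequences were not used here.

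The calls for 2 µg against control were tested on simulated data with 8018 genes and 20 runs, each with 200 changed genes and spreads like those of the fit. The share of changed genes recovered was 17.4% at a log2 change of 0.5, 92.4% at 1 and 100% at 2. Of all calls, 5.17% were false, and 0 had the wrong sign. A simulated comparison with no change gave 0.2 calls per run. A list moved by 0.3 was called in 20 of 20 runs, with 0 calls of other lists. In the data 3335 genes were called at 2 µg, against 200 changed genes in each run. The Benjamini-Hochberg adjustment is less strict when more genes differ, so the recovered shares do not describe the calls in the data. Genes were drawn independently of each other in these runs. They therefore do not show how list calls behave where members are correlated, as in the ATF4 list with an estimated correlation of 0.129. Figures were drawn with matplotlib from the same tables.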

Results

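The data were 6 arrays of HEK293T cells, with 2 untransfected controls, 2 from cells given 2 µg of the cluster plasmid and 2 from cells given 4 µg. Each probe was read from a median of 40 beads, and the median standard error of the bead intensity was between 4.22% and 4.46% of the signal. On the control arrays 9558 and 9721 of 48701 probes were detected, on the 2 µg arrays 9278 and 9553, and on the 4 µg arrays 9768 and 10371. Across tested genes, which are not independent replicates, the normalized log2 values of duplicates correlated at 0.9916 in the control, 0.9898 at 2 µg and 0.9941 at 4 µg. Between groups these correlations were lower, from 0.9481 to 0.9493 for control and 2 µg, from 0.9716 to 0.9731 for control and 4 µg, and from 0.9796 to 0.9835 for the doses. All log2 fold changes below come from duplicates (n = 2 arrays per group), and their errors are standard errors. Each gene described as rising or falling did so with both arrays of one group above both arrays of the other. That separation was common, with 5580 of 8018 tested genes at 2 µg, 5277 at 4 µg and 4595 between the doses.

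The comparison of 2 µg with the control asked which genes differed in cells that carried the plasmid of the microRNA cluster. CXCL8, which encodes the neutrophil attractant interleukin 8, rose by 3.88 on the log2 scale (SE 0.12), a 14.8-fold rise (adjusted p = 9.92e-08). TNFAIP3, a feedback inhibitor of NF-kB signalling, was detected on 0 of 2 control arrays and was at least 8.39-fold higher (adjusted p = 4.67e-07). IGFBP5, an insulin-like growth factor binding protein, fell by 2.94 (SE 0.14), a 7.70-fold fall (adjusted p = 1.09e-06). HSPA1B, an inducible cytosolic chaperone whose sequence is nearly identical to that of HSPA1A, was 5.18-fold lower (adjusted p = 1.86e-06).

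Other genes with the largest rises at 2 µg were PPP1R15A, the phosphatase subunit that reverses the phosphorylation of eIF2alpha, with a log2 change of 2.55 (SE 0.13), and ATF3, a stress-induced transcription factor, with 2.45 (SE 0.15). ETV5, a transcription factor of the ERK pathway, rose by 3.14 (SE 0.14) and IL32, a cytokine, by 2.69 (SE 0.13), with both detected on 1 of 2 control arrays. Detected on 0 of 2 control arrays were CCL20, a chemokine, which was at least 5.14-fold higher, INHBE, an activin subunit, at least 4.51-fold higher, RASSF1, a scaffold of Hippo signalling, at least 3.66-fold higher, and TMEM52B, at least 2.23-fold higher. Among the largest falls, HES5, a target of Notch, fell by 2.52 (SE 0.13) and UBE2L6, an enzyme of ISG15 conjugation, fell by 2.15 (SE 0.13). LMTK3 fell by 2.20 (SE 0.19) and VASH1 fell by 2.18 (SE 0.14), with both detected on 1 of 2 arrays at 2 µg. Detected on 0 of 2 arrays at 2 µg were NEFL, the light neurofilament, which was at least 3.80-fold lower, ZNF467, at least 2.85-fold lower, MGAT3, a glycosyltransferase, at least 2.81-fold lower, and RALGPS1, at least 2.32-fold lower. The largest adjusted p among these genes was 2.77e-05 (LMTK3). Of 8018 genes tested by limma, 3335 were called at 2 µg, with 1745 higher and 1590 lower, and 2047 of them differed by over 1.5-fold. The count at an unadjusted p under 0.05 was 3980.

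Genes that ATF4 raises when eIF2alpha is phosphorylated were higher at 2 µg as a list. Of 32 members tested, 26 rose, 2 fell and 4 were not called, and the counts adjusted over the list alone were also 26 and 2. The median log2 change was 0.83 (camera adjusted p = 8.62e-10; adjusted p = 0.221 with an estimated correlation). TRIB3, a pseudokinase, rose by 2.44 (SE 0.13, adjusted p = 1.7e-06), and DDIT3, the stress transcription factor CHOP, by 2.17 (SE 0.14, adjusted p = 5.49e-06). TXNIP was among the members that fell, with a log2 change of -0.42 (adjusted p = 0.0243), a call that ended without control replicate 1 (adjusted p = 0.11), control replicate 2 (0.0589) or 2 µg replicate 2 (0.104), and with median scaling over all probes (0.086). The immediate early and JNK response list was also higher, with 18 of 24 members rising and 0 falling, and the same counts adjusted over the list alone (camera adjusted p = 2.73e-08; adjusted p = 0.137 with an estimated correlation). Its median log2 change was 0.79, and 0.76 with members undetected in the control at their bound. GADD45B, a growth arrest gene, rose by 2.38 (SE 0.14), FOS by 1.78 (SE 0.18) and CCN1, a matrix protein, by 1.49 (SE 0.13). In the NF-kB response list 11 of 14 members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 7.25e-09; adjusted p = 0.137 with an estimated correlation). The median log2 change was 1.70, and 1.14 with undetected members at their bound, and TNF, which was detected on 0 of 2 control arrays, was at least 2.02-fold higher (adjusted p = 9.48e-06).

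Histone genes rose together at 2 µg, with 10 of 12 members higher, 0 lower and the same counts adjusted over the list alone (camera adjusted p = 5.58e-06; adjusted p = 0.137 with an estimated correlation). The median log2 change was 1.05, or 0.98 with undetected members at their bound. H4C8 rose by 2.10 (SE 0.12), H4C14 by 2.06 (SE 0.15) and H1-2 by 1.18 (SE 0.13), and probes of histone genes can bind near-identical copies. Of 40 genes of G1/S and DNA replication, 16 rose, 1 fell and 23 were not called, and 18 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.00427; adjusted p = 0.422 with an estimated correlation). CDT1, a licensing factor of replication origins, rose by 1.11 (SE 0.13), and E2F1, a transcription factor of S phase genes, by 0.80 (SE 0.13). The camera call of this list ended without 2 µg replicate 1 (adjusted p = 0.0592). Of 41 genes of G2/M and mitosis, 9 rose and 3 fell, or 8 and 3 adjusted over the list alone, and the list was not called (camera adjusted p = 0.0964).

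Respiratory chain genes were lower at 2 µg. Of 48 members of the oxidative phosphorylation list, 20 fell, 0 rose and 28 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.000603; adjusted p = 0.334 with an estimated correlation). COX6B1, a subunit of cytochrome c oxidase, fell by 1.06 (SE 0.13) and NDUFA3, a subunit of complex I, fell by 0.80 (SE 0.13). Of 19 cytosolic heat shock genes 10 fell and 3 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0158; adjusted p = 0.233 with an estimated correlation), and HSPB1, a small heat shock protein, fell by 1.44 (SE 0.13). Of 29 genes of glycolysis and hypoxia 15 fell and 5 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0324; adjusted p = 0.332 with an estimated correlation). PFKFB4, a regulator of glycolysis, fell by 1.27 (SE 0.12), while BHLHE40, a transcription factor, rose by 1.57 (SE 0.13). The glycolysis call ended without control replicate 1 (adjusted p = 0.0737) and without 2 µg replicate 2 (adjusted p = 0.0624). GAPDH, often used as a control gene, fell by 0.69 (SE 0.16, adjusted p = 0.0059), as it did under each scaling, and all 3 of its kept probes were lower. ACTB, another common control gene, had a log2 change of -0.13 (SE 0.14, adjusted p = 0.49) and was negative under each scaling, and it passed the threshold with the authors' processed values (adjusted p = 0.0295) and with median scaling over the tested genes (adjusted p = 0.0217). The other 2 kept probes of ACTB disagreed with each other, with 0.07 and -0.56.

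Among markers of other cell types at 2 µg, 5 of 6 fibroblast markers fell and 0 rose (camera adjusted p = 0.00147; adjusted p = 0.221 with an estimated correlation), among them the collagen gene COL5A1, which fell by 1.38 (SE 0.13). Of 4 epithelial markers 3 fell and 0 rose (camera adjusted p = 0.00547; adjusted p = 0.233 with an estimated correlation), and the keratin gene KRT19 fell by 1.80 (SE 0.15). Of 7 neuronal markers 3 fell, NEFL among them, and 1 rose, SNAP25, a synaptic fusion protein detected on 0 of 2 control arrays and at least 2.01-fold higher (camera adjusted p = 0.217 for the list). Of 2 haematopoietic markers tested 1 rose, CD68, a lysosomal protein of macrophages, by 0.79 (SE 0.16; camera adjusted p = 0.28 for the list). Adjusted over the list alone, the counts of these 4 lists were the same.

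The published targets of the cluster's microRNAs moved in both directions at 2 µg. So did the tested genes at large, of which 41.6% were called, 1745 higher and 1590 lower. Of 21 miR-23a targets 8 rose and 1 fell, or 9 and 1 adjusted over the list alone, and the list was higher (camera adjusted p = 0.0158; adjusted p = 0.256 with an estimated correlation). IRF1, an interferon transcription factor, rose by 1.16 (SE 0.15), and PLAU, the urokinase activator of plasminogen, was detected on 0 of 2 control arrays and was at least 1.86-fold higher. The camera call of this list ended without 2 µg replicate 2 (adjusted p = 0.0624) and when only genes detected on all 6 arrays were tested (adjusted p = 0.158). Of 27 miR-27a targets 9 fell and 6 rose, or 10 and 6 adjusted over the list alone (camera adjusted p = 0.324). SEMA6A fell by 1.32 (SE 0.13), the nuclear receptor RXRA fell by 1.18 (SE 0.14) and the growth factor receptor IGF1R fell by 1.01 (SE 0.14), while CYP1B1, a cytochrome P450, rose by 0.66 (SE 0.14). Of 30 miR-24 targets 11 rose and 4 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.166). TRIB3 rose, ST7L was detected on 0 of 2 control arrays and was at least 2.06-fold higher, and INSIG1, a sterol sensor, fell by 1.85 (SE 0.13). FADD, an adaptor of death receptors and a published miR-27a target, had a log2 change of -0.42 (SE 0.14, adjusted p = 0.0315). Its call ended without control replicate 1 (adjusted p = 0.0684), control replicate 2 (0.139), 2 µg replicate 2 (0.166) or either 4 µg array (0.0509 each). It also ended with median scaling over all probes (0.115), with the authors' processed values (0.065), without a detection filter (0.0565) and in a fit of only the groups compared (0.0509). XIAP, an inhibitor of caspases and a published target of miR-23a and miR-24, was not tested, because its detection p-value was under 0.01 on 1 of 6 arrays.

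The remaining lists were not called at 2 µg. Of 27 genes of the endoplasmic reticulum 7 fell and 4 rose, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.247). HSPA5, the chaperone BiP, fell by 0.59 (SE 0.14, adjusted p = 0.00693), a call that ended without control replicate 1 (adjusted p = 0.0591), and SDF2L1 fell by 0.97 (SE 0.15), while XBP1, a transcription factor of the unfolded protein response, rose by 0.78 (SE 0.13). Of 26 apoptosis genes 4 rose, among them PMAIP1 by 0.76 (SE 0.13), and 2 fell, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.757). Of 21 p53 targets 7 rose and 4 fell (camera adjusted p = 0.595), with GADD45A higher by 2.05 (SE 0.17) and CDKN1A, the cell cycle inhibitor p21, lower, with a log2 change of -0.85 (SE 0.12). Of 24 interferon response genes 7 rose and 7 fell, or 8 and 8 adjusted over the list alone (camera adjusted p = 0.694). CXCL10, a chemokine detected on 0 of 2 control arrays, was at least 1.69-fold higher, while BST2, a membrane protein that tethers virus particles, fell by 2.11 (SE 0.13). Of 20 cholesterol synthesis genes 8 fell and 1 rose (camera adjusted p = 0.0521), and TM7SF2 fell by 1.08 (SE 0.14). Of 46 ribosomal protein genes 5 fell, among them RPL14 with a log2 change of -0.71 (SE 0.15), and 1 rose, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.204). Of 24 proteasome genes 3 fell, PSMA7 with a log2 change of -0.60 (SE 0.14), and 0 rose (camera adjusted p = 0.166). Of 20 genes of oxidative stress and metallothioneins 5 fell, among them MT1X, which was 1.99-fold lower, and 4 rose, among them the autophagy receptor SQSTM1 with 1.21 (SE 0.12; camera adjusted p = 0.247). Of 15 genes of microRNA machinery 5 rose and 2 fell, or 5 and 3 adjusted over the list alone (camera adjusted p = 0.469), with AGO3 higher by 0.85 (SE 0.15) and the silencing factor TNRC6B lower, with -1.19 (SE 0.17). Of 16 genes of TGF-beta and BMP signalling 4 rose and 3 fell, or 6 and 4 adjusted over the list alone (camera adjusted p = 0.595), and TGFBI, a matrix protein detected on 0 of 2 control arrays, was at least 1.75-fold higher. For the p53, cholesterol, proteasome and oxidative stress lists the counts adjusted over the list alone were the same.

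**Figure D1:**
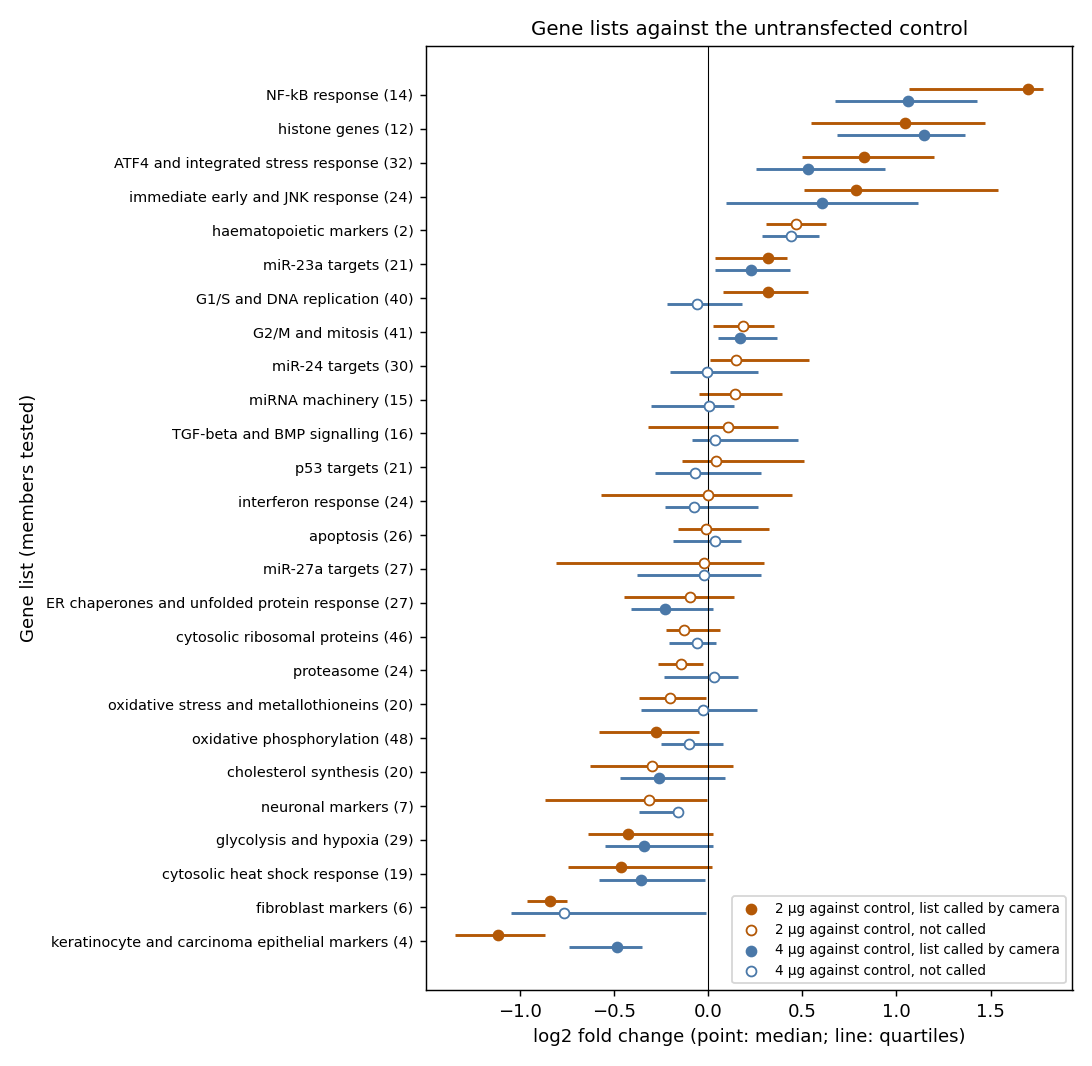
Median log2 fold change (points) and quartiles (lines) of the members of each of the 26 gene lists, for 2 µg and 4 µg against the untransfected control, with filled points where camera called the list with its preset correlation and the number of members tested in parentheses. The NF-kB response list had medians of 1.70 and 1.06, and 0 lists were called with an estimated correlation. The medians plot fitted values, and with undetected members at their bound those of this list were 1.14 and 0.75.

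The comparison of 4 µg with the control asked the same question at the higher dose. CXCL8 rose by 3.30 on the log2 scale (SE 0.12), a 9.88-fold rise (adjusted p = 5.27e-07), and FOS, an immediate early transcription factor, by 2.49 (SE 0.18), a 5.61-fold rise (adjusted p = 4.22e-05). TNFAIP3, detected on 0 of 2 control arrays, was at least 5.59-fold higher (adjusted p = 3.43e-06). TXNIP, a regulator of glucose uptake, fell by 1.49 (SE 0.13), a 2.80-fold fall (adjusted p = 0.000127), and NEFL fell by 1.84 (SE 0.18; adjusted p = 0.000256).

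Further rises at 4 µg were PPP1R15A by 2.17 (SE 0.13), PLA2G4C, a phospholipase, by 2.03 (SE 0.12), DDIT3 by 1.92 (SE 0.14) and BEST1, a chloride channel detected on 1 of 2 control arrays, by 1.78 (SE 0.13). Detected on 0 of 2 control arrays were INHBE, at least 4.51-fold higher, COG5, a Golgi protein, at least 2.34-fold higher, and RASSF1, at least 2.13-fold higher. HES5 fell by 1.44 (SE 0.13), UBE2L6 fell by 1.44 (SE 0.13), BST2 fell by 1.40 (SE 0.13), GAMT, an enzyme of creatine synthesis, fell by 1.35 (SE 0.12) and the channel protein PANX2 fell by 1.34 (SE 0.15). LRRC26 and TUBB4A were detected on 0 of 2 arrays at 4 µg and were at least 1.74-fold and 1.37-fold lower. The small RNA SNAR-A1 fell by 1.62 (SE 0.34, adjusted p = 0.00853), a call that ended without control replicate 2 (adjusted p = 0.08), without 4 µg replicate 1 (0.0527) and without a detection filter (0.0526). Of 8018 genes tested by limma 1760 were called at 4 µg, with 943 higher and 817 lower, 959 of them by over 1.5-fold, and 2940 had an unadjusted p under 0.05. The count fell to 783 without control replicate 1, 939 without control replicate 2, 732 without 4 µg replicate 1 and 696 without 4 µg replicate 2. Median scaling over all probes shifted the median log2 change of all tested genes from 0.03 to 0.18. The split of the calls, which includes that shift, changed to 1601 higher and 357 lower. It was 1558 and 717 with the authors' processed values, where the median was 0.083, and 771 and 1051 with median scaling over the tested genes, where it was -0.03.

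The ATF4 list was again higher at 4 µg, with 20 of 32 members rising and 1, TXNIP, falling, or 22 and 2 adjusted over the list alone, and a median log2 change of 0.53 (camera adjusted p = 5.64e-09; adjusted p = 0.189 with an estimated correlation). TRIB3 rose by 1.75 (SE 0.13) and ATF3 by 1.62 (SE 0.15). In the immediate early and JNK list 14 of 24 members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.09e-07; adjusted p = 0.156 with an estimated correlation). The median was 0.60, or 0.52 with undetected members at their bound, and GADD45B rose by 1.49 (SE 0.14) and CCN1 by 1.28 (SE 0.13). In the NF-kB list 11 of 14 members rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.34e-09; adjusted p = 0.0937 with an estimated correlation). TNF was at least 1.64-fold and CCL20 at least 2.36-fold higher, both detected on 0 of 2 control arrays. Of 12 histone genes 9 rose and 0 fell, or 11 and 0 adjusted over the list alone (camera adjusted p = 5.64e-09; adjusted p = 0.0937 with an estimated correlation). Their median was 1.15, or 1.11 with undetected members at their bound, with H4C14 higher by 1.75 (SE 0.15), H4C8 by 1.71 (SE 0.12) and H1-2 by 1.36 (SE 0.13).

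The G2/M and mitosis list was higher at 4 µg, with 5 of 41 members rising and 0 falling, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0186; adjusted p = 0.189 with an estimated correlation). ANLN, a cytokinesis gene, rose by 0.63 (SE 0.17), and the kinase genes NEK2 and PLK1 by 0.55 (SE 0.14) and 0.53 (SE 0.13). The adjusted p of ANLN was 0.176 without control replicate 2, 0.171 without 4 µg replicate 1, 0.0541 without 4 µg replicate 2 and 0.0818 without a detection filter. That of NEK2 was 0.0708, 0.0855 and 0.159 without control replicate 1, control replicate 2 and 4 µg replicate 1, and 0.0555 with no background correction, and that of PLK1 was from 0.0517 to 0.13 without any of the 4 arrays compared. Of 40 G1/S and DNA replication genes 3 rose, CDT1 by 0.73 (SE 0.13), and 4 fell, cyclin gene CCNE1 with a log2 change of -0.80 (SE 0.14), or 2 and 4 adjusted over the list alone (camera adjusted p = 0.492). Heat shock genes were lower, with 8 of 19 falling and 0 rising, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.00517; adjusted p = 0.189 with an estimated correlation). HSPA1B fell by 1.04 (SE 0.13) and HSPB1 fell by 0.79 (SE 0.13). Endoplasmic reticulum genes were lower as a list, with 6 of 27 falling and 2 rising, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.0235; adjusted p = 0.189 with an estimated correlation), and SDF2L1 fell by 0.99 (SE 0.15). HSPA5 had a log2 change of -0.51 (SE 0.14, adjusted p = 0.0246), a call that ended without control replicate 1 (adjusted p = 0.153), 4 µg replicate 1 (0.0942) or 4 µg replicate 2 (0.143), without a detection filter (0.052) and with median scaling over all probes (0.224).

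Cholesterol synthesis genes were lower at 4 µg, with 7 of 20 falling and 0 rising and the same counts adjusted over the list alone (camera adjusted p = 0.0235; adjusted p = 0.189 with an estimated correlation). INSIG1 fell by 1.16 (SE 0.13) and TM7SF2 fell by 0.74 (SE 0.14), and the list's call ended without control replicate 2 (adjusted p = 0.0583). Of 29 genes of glycolysis and hypoxia 8 fell and 3 rose, or 16 and 5 adjusted over the list alone (camera adjusted p = 0.00916; adjusted p = 0.215 with an estimated correlation). PFKFB4 fell by 0.72 (SE 0.12) and BHLHE40 rose by 1.17 (SE 0.13). GAPDH had a log2 change of -0.59 (SE 0.16, adjusted p = 0.0242) and was negative under each scaling. Its call ended without control replicate 1 (adjusted p = 0.0822), control replicate 2 (0.117), 4 µg replicate 1 (0.0945) or 4 µg replicate 2 (0.116) and without a detection filter (0.0674). ACTB had a log2 change of -0.21 (SE 0.14, adjusted p = 0.311), negative under each scaling, and it passed the threshold with the authors' processed values (adjusted p = 0.0214) and with median scaling over the tested genes (adjusted p = 0.0169), while its other kept probes had -0.34 and -0.97. Of 48 oxidative phosphorylation genes 3 fell and 0 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.0619), and COX6B1 had a log2 change of -0.66 (SE 0.13, adjusted p = 0.00672, and 0.0645 without 4 µg replicate 2).

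Among markers of other cell types at 4 µg, 4 of 6 fibroblast markers fell, COL5A1 with a log2 change of -1.11 (SE 0.13), and 1 rose, S100A4, a calcium-binding protein, by 1.09 (SE 0.14; camera adjusted p = 0.0643 for the list). Of 4 epithelial markers 2 fell and 0 rose, and KRT19 fell by 1.16 (SE 0.15). The epithelial list was called (camera adjusted p = 0.0138; adjusted p = 0.189 with an estimated correlation), but not without control replicate 2 (adjusted p = 0.0621) or without a detection filter (adjusted p = 0.137). Of 7 neuronal markers SNAP25, detected on 0 of 2 control arrays, was at least 1.48-fold higher and 1, NEFL, fell, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.208). Of 2 haematopoietic markers 1 rose, CD68 by 0.74 (SE 0.16; camera adjusted p = 0.23 for the list), and the adjusted p of CD68 was 0.0596 without control replicate 1, 0.06 without control replicate 2 and 0.0827 without 4 µg replicate 2. The fibroblast, epithelial and haematopoietic counts were the same adjusted over the list alone.

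Of the published targets at 4 µg, 5 of 21 miR-23a targets rose and 0 fell, with the same counts adjusted over the list alone, and the list was higher (camera adjusted p = 0.00984; adjusted p = 0.189 with an estimated correlation). IRF1 rose by 0.89 (SE 0.15), the coactivator gene PPARGC1A, detected on 1 of 2 control arrays, by 0.98 (SE 0.18), and PLAU, detected on 0 of 2 control arrays, was at least 1.54-fold higher. The list was not called when only genes detected on all 6 arrays were tested (adjusted p = 0.158). Of 27 miR-27a targets 4 fell and 3 rose, or 7 and 4 adjusted over the list alone (camera adjusted p = 0.544), with SEMA6A lower by a log2 change of -0.96 (SE 0.13) and the Wnt antagonist SFRP1 by -0.69 (SE 0.12). FADD had a log2 change of -0.02 (SE 0.14, adjusted p = 0.921). Of 30 miR-24 targets 6 rose and 2 fell, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.91), and ST7L, detected on 0 of 2 control arrays, was at least 1.74-fold higher.

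The other lists were not called at 4 µg. Of 26 apoptosis genes 2 rose and 1 fell, or 0 and 0 adjusted by limma over the list alone, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.982). Of 21 p53 targets 4 rose, GADD45A by 1.27 (SE 0.17), and 4 fell, or 5 and 4 adjusted over the list alone (camera adjusted p = 0.803), and CDKN1A fell by 0.91 (SE 0.12). Of 24 interferon response genes 5 rose and 5 fell, with CXCL10, detected on 0 of 2 control arrays, at least 1.76-fold higher and IFITM2, a membrane protein that restricts virus entry, lower by a log2 change of -0.86 (SE 0.13; camera adjusted p = 0.523). Of 46 ribosomal protein genes 2 fell, RPL14 with -0.81 (SE 0.15), and 0 rose, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.152). Of 24 proteasome genes 0 rose and 0 fell by limma, with 7 at an unadjusted p under 0.05 (camera adjusted p = 0.737), and PSMD1 had the smallest adjusted p, 0.0643. Of 20 genes of oxidative stress and metallothioneins 4 fell, MT1X with -0.94 (SE 0.14), and 2 rose, SQSTM1 by 1.28 (SE 0.12; camera adjusted p = 0.553). Of 15 microRNA machinery genes 3 fell and 1 rose, or 4 and 2 adjusted over the list alone (camera adjusted p = 0.569), and TNRC6B had a log2 change of -0.86 (SE 0.17, adjusted p = 0.00643, and 0.0599 without control replicate 1). Of 16 TGF-beta and BMP genes 5 rose and 1 fell (camera adjusted p = 0.23), with TGFBI, detected on 0 of 2 control arrays, at least 1.16-fold higher. For the interferon, proteasome, oxidative stress and TGF-beta lists the counts adjusted over the list alone were the same.

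**Figure D2:**
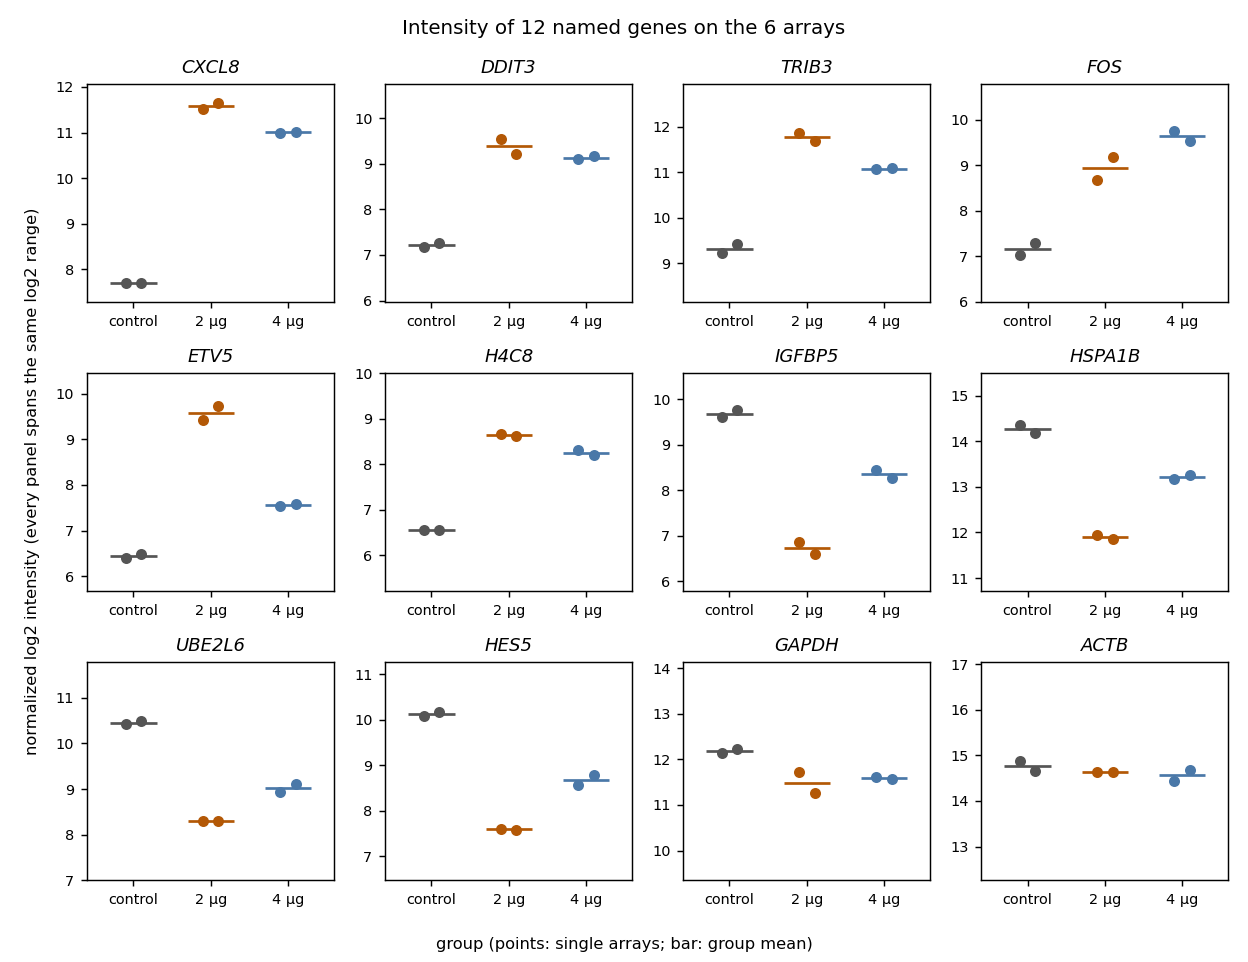
Normalized log2 intensity of 12 named genes on the 6 arrays, with single arrays as points and group means as bars, and with panels that span the same log2 range. For CXCL8 the arrays of both doses lay above both control arrays, by 3.88 at 2 µg and 3.30 at 4 µg, while ACTB, shown by 1 of its 3 kept probes, had changes of -0.13 and -0.21, which did not pass the threshold.

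The mean of both doses was compared with the control, and camera called 12 of 26 lists, 6 higher and 6 lower. The lists higher were the ATF4 response, with 26 members rising and 2 falling, the NF-kB response (11 and 0), the immediate early and JNK response (15 and 0), histone genes (10 and 0), miR-23a targets (7 and 1) and G2/M genes (10 and 2). Those lower were oxidative phosphorylation, with 13 members falling and 0 rising, the heat shock response (9 and 3), glycolysis and hypoxia (15 and 5), cholesterol synthesis (8 and 0), fibroblast markers (4 and 1) and epithelial markers (3 and 0). With an estimated correlation 0 of them were called, the smallest value being adjusted p = 0.13 with an estimated correlation. For this mean limma called 3103 genes, with 1663 higher and 1440 lower, 1394 of them by over 1.5-fold, and 3876 had an unadjusted p under 0.05. Without control replicate 2 the count of genes was 2027, and with median scaling over all probes 66.3% of the calls were higher, against 53.6%.

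Most changes against the control were smaller at 4 µg than at 2 µg. The log2 fold changes correlated at 0.839 across 8018 genes, against a mean of 0.50 in simulations with no effect, in which the shared control arrays alone produce a correlation. The covariance was 0.189, or 0.178 above the simulated mean. Called at both doses were 1468 genes, at 2 µg only 1867 and at 4 µg only 292, which does not show that these differed between the doses. Of those called at both, 774 were higher, CXCL8 and DDIT3 among them, 691 were lower, HES5 and UBE2L6 among them, and 3 went in opposite directions. Because the doses share the control arrays, this overlap was not tested. Of 3627 genes called at either dose, 82.9% had the larger absolute log2 change at 2 µg, and a line through 0 had a slope of 0.611. Of the genes called at 4 µg, 65.2% had the larger change at 2 µg.

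**Figure D3:**
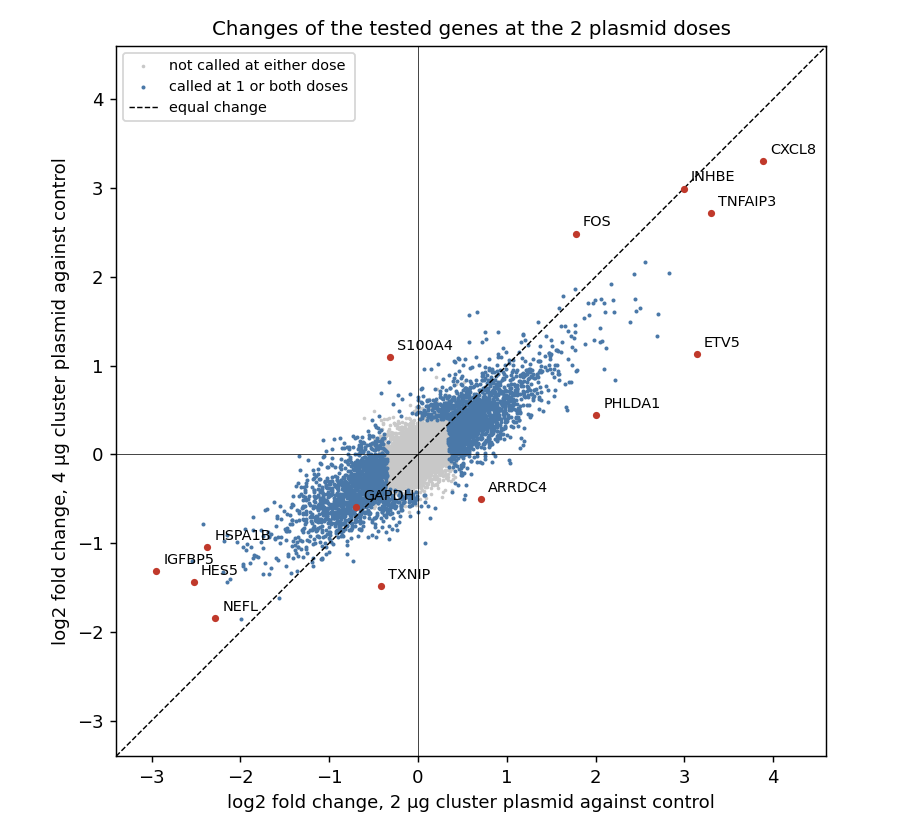
Log2 fold change of each of 8018 genes at 4 µg (vertical axis) and at 2 µg (horizontal axis) against the same untransfected control, with genes called at 1 or both doses in blue, named genes in red and a dashed line of equal change. Most called genes lie closer to 0 on the vertical axis, with a slope of 0.611, while FOS and TXNIP lie farther from 0 at 4 µg. Values of genes undetected in a group, such as TNFAIP3, INHBE, PHLDA1 and NEFL, are fitted values.

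The comparison of 4 µg with 2 µg asked whether the response depended on the dose. ETV5, a target of the ERK pathway, fell by 2.02 on the log2 scale (SE 0.14, adjusted p = 0.000233) and PHLDA1, another growth factor response gene, fell by 1.57 (SE 0.16, adjusted p = 0.0013). IGFBP5 was 3.09-fold higher at 4 µg than at 2 µg (log2 1.63, SE 0.14, adjusted p = 0.00123), which left it lower than in the control. HSPA1B was 2.51-fold higher at 4 µg than at 2 µg (adjusted p = 0.00125). S100A4 was 2.65-fold higher at 4 µg than at 2 µg (adjusted p = 0.0013), with a log2 change against the control of -0.32 (adjusted p = 0.107) at 2 µg, and both of its kept probes gave values alike.

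Also lower at 4 µg than at 2 µg were IL32, which fell by 1.36 (SE 0.13), and CYB5R2, a reductase detected on both 2 µg arrays and on 0 of 2 arrays at 4 µg, at least 2.03-fold lower. MGAT3 and ZNF467, detected on 0 of 2 arrays at 2 µg, were at least 1.22-fold and 1.66-fold higher at 4 µg than at 2 µg. ARRDC4, an arrestin family gene induced with TXNIP, fell by 1.21 (SE 0.13, adjusted p = 0.0013). Of 8018 genes tested by limma 705 were called, 419 higher and 286 lower at 4 µg, 466 of them by over 1.5-fold, and 2171 had an unadjusted p under 0.05. Of the 705, 627 had the larger absolute change against the control at 2 µg. Another 53 were called at 4 µg against the control and lay farther from it at 4 µg, 35 higher and 18 lower, among them TXNIP, which fell by 1.07 from 2 µg to 4 µg (SE 0.13, adjusted p = 0.00282). FOS was also among them, with a difference of 0.71 (SE 0.18, adjusted p = 0.0386), which was not called without any 1 of the arrays except 2 µg replicate 2 (adjusted p from 0.0571 to 0.221), nor without a detection filter (0.114) or in a fit of only the groups compared (0.0571). The count of called genes was 234 without 2 µg replicate 1, 93 without 4 µg replicate 1, 118 without 4 µg replicate 2 and 273 without a detection filter. With median scaling over all probes, which shifted the median difference of all genes from 0.00 to 0.15, the calls were 870 higher and 102 lower.

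Camera called 8 of 26 lists between the doses and 0 with an estimated correlation. Lower at 4 µg than at 2 µg were G1/S and DNA replication, with 11 of 40 members falling and 0 rising, or 18 and 0 adjusted over the list alone (camera adjusted p = 2.55e-08; adjusted p = 0.311 with an estimated correlation), and the ATF4 response, with 8 of 32 falling and 0 rising, or 13 and 0 adjusted over the list alone (camera adjusted p = 1.68e-06; adjusted p = 0.311 with an estimated correlation). E2F1 fell by 0.68 (SE 0.13, adjusted p = 0.013), with an adjusted p of 0.0576 without 2 µg replicate 1, 0.0776 without 4 µg replicate 1 and 0.0938 without 4 µg replicate 2. The NF-kB response was lower, with 7 of 14 falling and 0 rising, or 8 and 0 adjusted over the list alone (camera adjusted p = 1.59e-05; adjusted p = 0.311 with an estimated correlation), and CCL20 fell by 1.12 (SE 0.13, adjusted p = 0.00275). In the immediate early and JNK list, which was also lower, 9 of 24 fell and 2 rose, or 11 and 2 adjusted over the list alone (camera adjusted p = 0.000452; adjusted p = 0.311 with an estimated correlation). Of 30 miR-24 targets 5 fell and 2 rose, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0413; adjusted p = 0.311 with an estimated correlation). The miR-24 median was -0.12. With median scaling over all probes, which raised the median of all genes by 0.15, it was 0.02, or -0.13 relative to all genes. The list of miR-24 targets was not called without 2 µg replicate 1 (adjusted p = 0.13), without 4 µg replicate 2 (0.0555) or with only genes detected on all 6 arrays (0.0948).

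Higher at 4 µg than at 2 µg was oxidative phosphorylation, with 2 of 48 members rising and 0 falling, or 0 and 0 adjusted by limma over the list alone, with 14 at an unadjusted p under 0.05 (camera adjusted p = 0.000597; adjusted p = 0.482 with an estimated correlation). Epithelial markers were higher, with 3 of 4 rising and 0 falling (camera adjusted p = 0.0223; adjusted p = 0.311 with an estimated correlation), but not without 2 µg replicate 2 (adjusted p = 0.0681) or with only genes detected on all 6 arrays (adjusted p = 0.0948). Fibroblast markers were higher, with 2 of 6 rising, S100A4 among them, and 0 falling (camera adjusted p = 0.0413; adjusted p = 0.311 with an estimated correlation). Their call ended without control replicate 1 or control replicate 2 (adjusted p = 0.0611 each), 2 µg replicate 1 (0.165) or 4 µg replicate 2 (0.0531). It also ended with normexp background correction (0.0613), no background correction (0.0647), the authors' processed values (0.0637), no detection filter (0.229), median scaling over the tested genes (0.0678) and a fit of only the groups compared (0.0611). The epithelial and fibroblast counts were the same adjusted over the list alone. The heat shock list, with HSPA1B and 2 other members rising and 0 falling, was not called (camera adjusted p = 0.468). Of 21 p53 targets 4 fell and 0 rose, or 5 and 1 adjusted over the list alone (camera adjusted p = 0.077). Of 27 endoplasmic reticulum genes 0 rose and 0 fell by limma, with 4 at an unadjusted p under 0.05 (camera adjusted p = 0.468).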

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

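The tests of signal compression, of gene lists against a mixture of cells, of a gradient along the chip and of shared list members were chosen only after the result was seen, and the bound of the compression test and the genes of the gradient test were set anew after a first value.

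Of the 26 lists, 8 differed between the doses by camera with its preset correlation, and 0 with an estimated correlation (2 at an unadjusted p under 0.05, and 8 by fry). The mean log2 differences, 4 µg against 2 µg, were -0.442 for the NF-kB response, -0.349 for G1/S and DNA replication, -0.323 for the ATF4 response, -0.303 for the immediate early and JNK response, -0.163 for miR-24 targets, 0.191 for oxidative phosphorylation, 0.437 for fibroblast markers and 0.482 for epithelial markers. Each of these lists had moved the other way at 2 µg against the control on average, so each mean lay closer to the control at 4 µg.

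Most changes were smaller at 4 µg than at 2 µg. A narrower spread of raw signal on the 4 µg arrays was argued against. The standard deviation of their deposited log2 signal, with no background subtracted, was 1.03 times that of the other arrays. That ratio also depends on the background, and quantile normalization gives all arrays the same spread. It therefore does not decide on other forms of compression in the normalized values. A 2 µg response diluted by unchanged cells is a candidate explanation that stays open for most genes. The share of responding cells was not measured, and was taken as the one from 0 to 1 that left the fewest genes called. With 65% of cells responding as at 2 µg, 59 of 8018 genes (0.736%) differed from the mixture of levels, 32 above and 27 below. This met the bound of 1% set beforehand for the best share, while shares of 0.5 (1.45%) and 0.75 (1.53%) did not. Meeting it is weak support, because the share was fitted to the same data and small departures can go uncalled with duplicates. The lists were tested at the share of 65% against a weighted mean of log2 values. It is not the level that mixed cells would give but lies at or below it, which can make a list look higher but not lower. From that mean 2 lists differed with the preset correlation, G1/S genes lower (camera adjusted p = 1.9e-08) and histone genes higher (2.9e-05). With an estimated correlation 0 did (camera adjusted p = 0.47 and 0.4). Against the mixture of levels the median log2 difference was -0.272 for G1/S genes and 0.228 for histone genes, and camera did not test these. For the uneven lists dilution and a response that depends on dose therefore cannot be told apart. The dose itself stays open, was not tested apart from the share of cells that took up plasmid, and may act beside dilution. Dilution alone would not place genes farther from the control at 4 µg, as was called for 53 genes, TXNIP among them. Nor would it give the 3 genes called in opposite directions, or the 59 genes that differed from the mixture, false calls aside. For these genes, as called, the values argue against dilution as the only cause.

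The ATF4, immediate early and JNK, and NF-kB lists were higher by camera at both doses than in untransfected cells, with the preset correlation, while the heat shock list was lower, and 0 of these calls held with an estimated correlation (adjusted p from 0.0937 to 0.233). A steady gradient along the chip as the whole cause was argued against. Of 68 tested members of these 3 higher lists, 10 (14.7%) had a 2 µg mean between those of the control and 4 µg. Members were counted whether called or not, and the 2 µg arrays lay between the others on the chip. The share between was 33.4% of the genes called at 4 µg and 9.75% of those called at 2 µg. In part the 14.7% restates that these lists were lower at 4 µg than at 2 µg. The transfection procedure itself and the microRNA cluster cannot be told apart, because 0 vector-only arrays were among the groups. Either may have raised CXCL8, TNFAIP3 and the other members of these lists.

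Published miR-23a targets were higher as a list at both doses with the preset correlation, but not with an estimated correlation (adjusted p = 0.256 at 2 µg and 0.189 at 4 µg). IRF1 also stands on the interferon list and TNFAIP3 on the NF-kB list, and without them 19 members were left, with a mean log2 change of 0.29 at 2 µg and 0.27 at 4 µg, of which 6 rose and 1 fell at 2 µg and 3 rose and 0 fell at 4 µg. The p by camera was then 0.043 at 2 µg and 0.031 at 4 µg with the preset correlation, and 0.2 and 0.18 with an estimated correlation. Whether the shared members alone may account for the rise of the list cannot be told apart from a rise of the other targets. Camera gave different answers with its preset and its estimated correlation, and the cause of that difference was not tested. An effect of the microRNA itself stays open, as untested.

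Called in opposite directions at the 2 doses were 3 genes, with a called difference between the doses in each (for SEH1L not without 4 µg replicate 1, adjusted p = 0.0564). ARRDC4 had log2 changes of 0.70 at 2 µg (adjusted p = 0.00144) and -0.51 at 4 µg (adjusted p = 0.0178), and the call at 4 µg ended without control replicate 2 (adjusted p = 0.096), 4 µg replicate 1 (0.0876) or 4 µg replicate 2 (0.116), with median scaling over all probes (0.172) and with the authors' processed values (0.0524). The others were chosen after their values were seen, SEH1L with 0.39 (adjusted p = 0.0287) and -0.42 (adjusted p = 0.0358) and TMEM187 with -0.41 (adjusted p = 0.0386) and 0.69 (adjusted p = 0.00795). Of SEH1L the call at 2 µg ended without any 1 array (adjusted p from 0.0522 to 0.131) and that at 4 µg without any 1 of the control or 4 µg arrays (0.0728 to 0.196). That of TMEM187 ended at 2 µg without control replicate 1 (0.239), 2 µg replicate 2 (0.161) or either 4 µg array (0.0609 each), and at 4 µg without control replicate 2 (0.0604) or 4 µg replicate 2 (0.0503). Median scaling over all probes ended the calls of SEH1L at both doses (0.0725 and 0.403) and of TMEM187 at 2 µg (0.0508), as the authors' processed values did for SEH1L at 4 µg (0.104) and TMEM187 at 2 µg (0.055). A fit of only the groups compared ended both calls at 2 µg (0.0534 and 0.0609), and that of TMEM187 also ended with no background correction (0.0625) and without a detection filter (0.0719).

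Of 1566 detected probes without a gene name, which the comparisons of genes did not use, limma called 572 at 2 µg (214 higher), 315 at 4 µg and 120 between the doses.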

How the results depend on the processing

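Median scaling over the tested genes and the leaving out of arrays for the correlation of the doses were tests chosen only after the result was seen. Of the 11 alternatives to the processing or the fit, 1 fitted only the groups compared and gave no mean of the doses. Another tested every probe on its own, and of 10021 probes it called 3964 at 2 µg, 2060 at 4 µg, 776 between the doses and 3702 for their mean. Apart from that one, the counts of genes ran from 2856 to 3581 at 2 µg and from 1286 to 2275 at 4 µg. They ran from 273 to 972 between the doses, and from 2719 to 3429 for the mean of the doses. The lowest count between the doses, 273, came from leaving out the detection filter, which raised the number of genes tested from 8018 to 18774. With arrays left out in turn the counts ran from 2471 to 3093 at 2 µg, from 696 to 2002 at 4 µg, from 93 to 559 between the doses and from 2027 to 3202 for the mean of the doses, and each such fit had fewer arrays. The correlation of the doses ran from 0.804 to 0.846 over other processing and from 0.794 to 0.847 with arrays left out.

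With an estimated correlation camera called 0 lists at 2 µg, 0 at 4 µg, 0 between the doses and 0 for their mean, with 5, 5, 2 and 5 lists at an unadjusted p under 0.05, while fry called 21, 15, 8 and 17. That correlation is estimated per list with 3 residual degrees of freedom. A larger correlation between members does not explain the loss for the NF-kB list and the histone genes. Their estimated correlations were -0.00912 and -0.0701, under the preset 0.01. Even so, their unadjusted p by camera at 2 µg went from 5.58e-10 to 0.00708 and from 8.59e-07 to 0.0139. The cause of the loss was not tested further. With arrays left out, camera called from 9 to 12 lists at 2 µg, from 9 to 13 at 4 µg, from 6 to 9 between the doses and from 11 to 12 for the mean. No called named gene changed sign under the alternatives in which it was tested, and no list called for either dose or between the doses changed its camera direction or the sign of its mean, while the median of miR-24 targets between the doses was -0.12, and 0.02 with median scaling over all probes, which raised the median of all genes by 0.15, so relative to all genes this list did not turn. Of the named genes, 97 of 109 calls at 2 µg, 70 of 111 at 4 µg and 15 of 40 between the doses held in each of the 16 settings in which the gene was tested. Among these settings, leaving out either array of the group not compared repeats the fit of only the groups compared.

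Replicates of different groups share only a number, and the deviations of replicates from their group mean correlated at -0.041 (control and 2 µg), -0.093 (control and 4 µg) and 0.115 (both doses). With the number as a replicate block the counts were 3330 at 2 µg, 1753 at 4 µg, 709 between the doses and 3084 for their mean. No paired reading was made of them. A planned test of seed matches in 3′ UTRs was not run. Signal over background limited the rest, since 9278 to 10371 of 48701 probes were detected per array, the offset of 16 shrinks folds near background, and XIAP was not tested.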

Other observations

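The tests of ERK feedback genes, alone and against a mixture of cells, and of snoRNA host genes, and the genes named in this part, were chosen only after the result was seen, and the adjustment of the ERK tests together with the 26 lists was added after their first values.

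Some genes lay farther from the control at 4 µg than at 2 µg. COLEC11, a secreted lectin of innate immunity, rose by 0.57 at 2 µg (adjusted p = 0.00457) and by 1.57 at 4 µg (SE 0.13, adjusted p = 7.5e-05), and the difference between the doses was called too (adjusted p = 0.00328). GPNMB, a membrane glycoprotein of lysosomes, was detected on 0 of 2 control arrays, 0 of 2 arrays at 2 µg and both at 4 µg, where it was at least 1.54-fold higher than in the control (adjusted p = 0.000127). MTMR2, a phosphatase of phosphoinositides, had a log2 change of 0.08 at 2 µg (adjusted p = 0.671) and fell by 1.00 at 4 µg (SE 0.14, adjusted p = 0.00141), with a called difference between the doses (adjusted p = 0.00374). Both arrays of the 4 µg group lay on the same side of all control arrays for each of these genes. That also held for 5277 of 8018 tested genes, so it adds little. Leaving out any 1 array ended none of these calls.

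ETV5 and PHLDA1, which the ERK pathway induces, were lower at 4 µg than at 2 µg, and a candidate explanation is a lower output of that pathway at 4 µg. Of 16 other genes of ERK feedback, listed from general knowledge, 12 were tested. Among them IER3, DUSP4, DUSP5 and FOSL1 also stand on the immediate early and JNK list, so the results of these lists overlap. Of the 12, 8 fell and 0 rose from 2 µg to 4 µg, with a mean log2 difference of -0.65 (the unadjusted p by camera was 1.4e-09, and 0.031 with an estimated correlation). Adjusted together with the 26 lists, these values were 1.9e-08 and 0.28. EPHA2, an ephrin receptor, fell by 0.97 (adjusted p = 0.00507), SPRED2, an inhibitor of the pathway, fell by 0.83 (adjusted p = 0.011, and 0.0933 without 4 µg replicate 1), and ETV4, detected on both 2 µg arrays and 0 of 2 at 4 µg, was at least 1.65-fold lower. Against the control 10 rose and 0 fell at 2 µg, with a mean of 0.77, while 2 rose and 1 fell at 4 µg, with a mean of 0.12. Other genes that the ERK pathway induces went the other way between the doses, FOS with 0.71 (adjusted p = 0.0386) and FOSB with 0.68 (adjusted p = 0.0313). Neither was called without 2 µg replicate 1, 4 µg replicate 1 or 4 µg replicate 2 (adjusted p from 0.0546 to 0.225) or without a detection filter (0.114 and 0.0895), FOS also not without either control array or in a fit of only the groups compared (0.0571 each), and FOSB also not without 2 µg replicate 2 (0.111).

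Against the mixture of levels with 65% of responding cells, the ERK feedback genes were lower by 0.45 on average. Of the 12 tested, 12 lay below it, and 2 were called on their own. Camera was run against a weighted mean of the log2 values of 2 µg and control. That mean is not the level that mixed cells would give but lies at or below it. The choice of this reference therefore cannot have made the list look lower. The unadjusted p by camera was 1.5e-08, and 0.036 with an estimated correlation. Adjusted together with the 26 lists, these values were 2e-07 and 0.42. A lower output of the pathway and a 2 µg response diluted by unchanged cells cannot be told apart for this list. Camera did not test the mixture of levels, and its answer differed between the preset and the estimated correlation, for a reason that was not tested. Phosphorylated ERK was not analysed here.

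SNHG15, a host transcript of small nucleolar RNA, rose by 2.05 at 2 µg (SE 0.13, 4.15-fold, adjusted p = 3.93e-06) and by 1.42 at 4 µg (SE 0.13, adjusted p = 0.00014). The difference between the doses was -0.63 (adjusted p = 0.0163), a call that ended without 2 µg replicate 1 (adjusted p = 0.0597), 4 µg replicate 1 (0.143) or 4 µg replicate 2 (0.0777) and with median scaling over all probes (0.0623). SNHG11, another host transcript, rose by 1.26 at 2 µg (adjusted p = 7.07e-05) and by 0.93 at 4 µg (adjusted p = 0.00133). SNHG5 had log2 changes of 0.39 (adjusted p = 0.0497) and 0.13 (adjusted p = 0.558), and its call at 2 µg ended without any 1 array except 2 µg replicate 1 (0.0585 to 0.24), with median scaling over all probes (0.0973) or over the tested genes (0.0711), without a detection filter (0.0865) and in a fit of only the groups compared (0.0772). Whether snoRNA host genes rise together as a class, as they might when translation falls and slows the decay of such transcripts, stayed open, because 2 of 21 other host genes were tested.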
